A study of Mus musculus with 4 samples.

How the data were processed

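Bone marrow cells of 10-week-old mice were profiled by droplet single-cell RNA sequencing at the 3' end of transcripts (10x Genomics Chromium, library and gel bead kit version 3.1, per the labels' protocols). The 4 libraries fell into 2 groups of 2 by their genotype labels: wild type (WT) and YAP1 heterozygote. Per the labels, the cells were flow-sorted nucleated bone marrow cells, and the sort gates were not given in the sources used here. The labels do not say that the replicates came from separate animals. The sex-linked transcripts given with the results show that the 2 libraries of a group do not hold the same animal. The spread behind the p-values thus holds differences between animals and sexes as well as technical ones.

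The authors deposited for each library a matrix of UMI counts per gene and barcode, a list of 32544 genes with Ensembl identifiers and symbols, and the barcodes called as cells. The values were whole-number counts with no normalization. Per the file headers the counts were written by Cell Ranger 5.0.0, while the submitters' processing notes list Cell Ranger 3.0.0, Seurat 4.3.0 and the genome builds GRCm38 and mm10; these versions differ, and which of them made the counts could not be settled from the files. The lowest UMI count of a deposited barcode was 500 or 501 in every library. A UMI count at the 3' end does not separate alleles, so a transcript from a changed Yap1 allele can still be counted and the Yap1 level checks no genotype here. Gene positions were taken by Ensembl identifier from GENCODE release M21 (GRCm38).

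Barcodes with at least 500 UMIs, at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 0.8% per 1000 barcodes) and removed; it marked between 3.383% and 4.433% of the barcodes of a library that passed these limits. The kept cells numbered 12418 and 11367 in WT replicates 1 and 2, and 10565 and 13214 in YAP1 heterozygote replicates 1 and 2. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, ranked over libraries, gave 30 principal components, a graph of 15 nearest neighbours and 33 Leiden clusters (resolution 1.0), with no integration of libraries. Immunoglobulin and T cell receptor variable segments and sex chromosome genes were left out of the clustering. Clusters were named from fixed marker lists, as "-like" cells; the name was the list with the highest mean marker level, or the one of the 3 best lists with the most markers among the 10 leading genes of the cluster. A cluster whose leading genes pointed to a list outside these, or with fewer than 3 detected markers, stayed unnamed. Cluster 30, led by Ace, Adgre4 and Cd300e, stayed unnamed. Because the classes were rebuilt here, shares are not comparable with shares from another annotation.

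Numbers of cells per class were compared with edgeR 4.0.16 (quasi-likelihood test, offset by the kept cells of a library), with an exact two-sided permutation test of the 4 shares beside it. For gene expression, UMI counts were summed per library and class and tested with edgeR's quasi-likelihood test (filterByExpr, TMM factors, Benjamini-Hochberg adjustment over the genes of a class, threshold 0.05) in each class with at least 20 cells in every library. Log2 fold changes are YAP1 heterozygote minus WT, and CPM values use the UMIs of the class in a library as the total and are given as mean ± SD of 2 libraries. Gene lists with at least 5 tested genes were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01), adjusted over all lists and classes; camera with an estimated correlation and fry were run beside it. The 31 lists, the markers, the tests and the rule for named genes were fixed before the data were examined; 3 list genes were renamed to the symbols in the files (Ccn1, Ccn2, Mrtfa). The rule took Yap1, Wwtr1 and Myh9, and per class up to 4 genes in each direction (12 in the megakaryocyte-like class and in the class with the most calls) with the largest change among called genes with an average log2 CPM of at least 4 and no overlap between groups, without gene models, variable segments and sex chromosome genes. For lists past the threshold it took up to 4 members: the called ones, otherwise the most highly expressed.

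Intervals on shares are Wilson intervals at the 95% level, and intervals on count ratios are exact Poisson intervals at that level; both, and the upper limit of 3 counts that a count of 0 allows, cover counting error only. Simulated data were drawn from the means, dispersion trend and library sizes of the megakaryocyte-like class (9685 genes). In them the gene test recovered 13.9% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 94.4% of those changed 4-fold. False calls made up 3.68% of the calls. In the T cell-like class (9147 genes) the shares were 9.95%, 54.7% and 89.9%, and in the mature neutrophil-like class (9759 genes) 15.4%, 62.7% and 94.9%. Each gene took the dispersion of the trend rather than its own, and genes were drawn independently. Recovery by the gene test in these data may thus be lower. The list test found the changed NF-kB list in 9 of 9 simulations of a log2 change of -0.7. Genes were drawn independently there, so these simulations do not show how the list test behaves with correlated genes. The share test found a megakaryocyte-like share lowered to 0.5 of its level in 12 of 20 simulations. These used the same fixed dispersion for every class rather than that of the data, so the recovery in these data may differ.

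Alternatives were a replicate block, each library left out in turn, DESeq2 1.42.0 (Wald test) and its size factors, no filter on low counts, sums thinned to the shallowest library, doublets kept, a stricter cell filter (500 genes, 5% mitochondrial UMIs), Leiden resolution 2.0, each library clustered alone, TMM factors over classes and all deposited barcodes. Added after the data were seen were sums without the cell holding the most UMIs of a gene in each library, mature neutrophil-like cells without cluster 2, NK cell or ILC-like cells of cluster 24 alone, subtraction of neutrophil RNA, a total without erythroid classes, and an estimated correlation with the block. Versions of other tools were Python 3.11.15, igraph 0.11.9 and R 4.3.3. Replicates of a group were compared before use; the chi-square statistic per degree of freedom over genes was 143 for WT and 52.3 for YAP1 heterozygote libraries, so the 2 libraries of a group were not copies of each other. Libraries of different groups were not compared in this way.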

Results

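Single-cell transcriptomes of bone marrow were compared between WT mice and mice with 1 changed copy of Yap1, the transcriptional coactivator at the end of the Hippo pathway. The series asks how cell percentages and gene expression differ between the genotypes, in a study on platelet formation, YAP1 and MYH9, the non-muscle myosin heavy chain. The libraries held 114943163 and 115773607 UMIs in WT replicates 1 and 2, and 112806900 and 119855112 UMIs in YAP1 heterozygote replicates 1 and 2, with 20091, 20193, 19911 and 20143 detected genes. Kept cells had median UMI counts of 5855.5, 6266.0, 6747.0 and 5517.0 in that order. In both groups, replicate 1 expressed the Y-linked gene Ddx3y (100.491 CPM in WT, 67.837 CPM in YAP1 heterozygote) and replicate 2 expressed Xist (885.239 CPM in WT, 864.005 CPM in YAP1 heterozygote). Each group thus held 1 library of each kind, and differences within a replicate number compare libraries of the same kind.

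Yap1 itself (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, GRCm38) was barely detected in bone marrow cells of either genotype. The kept cells held 6 and 7 Yap1 UMIs in the WT libraries and 0 and 6 in the YAP1 heterozygote libraries; a count of 0 in YAP1 heterozygote replicate 1 allows up to 0.0284 CPM. The ratio of YAP1 heterozygote to WT was 0.461 (exact Poisson interval 0.144 to 1.3), and a difference was not detectable at this depth. Its paralog Wwtr1 (TAZ; chromosome 3, 57455649 to 57575910) had 29 UMIs in WT and 18 in YAP1 heterozygote cells (ratio 0.62, interval 0.324 to 1.16). Neither gene passed the filter on low counts, and the 3' counts cannot tell the Yap1 alleles apart.

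Myh9 (ENSMUSG00000022443, chromosome 15, 77760587 to 77842175) was expressed at similar levels in both genotypes. Over all kept cells it stood at 355 ± 34.4 CPM in WT and 362 ± 43.8 CPM in YAP1 heterozygote libraries (SD, n = 2 each), a log2 fold change of 0.05 (SE 0.118, edgeR adjusted p = 0.999). In megakaryocyte-like cells the values were 366 ± 23.4 CPM and 343 ± 8.05 CPM, a log2 fold change of -0.08 (SE 0.129, edgeR adjusted p = 1). Myh9 was called in none of the 17 classes tested with edgeR. Over all cells its sign turned without WT replicate 2 (-0.06) and without YAP1 heterozygote replicate 1 (-0.0729).

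No cell class changed its share between the genotypes past the threshold. Megakaryocyte-like cells, marked by Pf4, Itga2b and Vwf and the source of platelets, made up 1.003 ± 0.086% of WT cells and 0.754 ± 0.089% of YAP1 heterozygote cells (SD, n = 2 each). In single libraries their share was 0.942% (Wilson interval 0.787 to 1.128%) and 1.06% (0.892 to 1.27%) in WT, and 0.691% (0.55 to 0.868%) and 0.817% (0.678 to 0.986%) in YAP1 heterozygote replicates 1 and 2. Macrophage-like cells, marked by C1qa, Vcam1 and Cd5l, stood at 0.481 ± 0.071% in WT and 1.124 ± 0.305% in YAP1 heterozygote bone marrow, 2.335 times the WT share. Mature neutrophil-like cells, the largest class, stood at 28.15 ± 1.422% and 27.08 ± 0.758%.

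For megakaryocyte-like cells the log2 fold change of the share was -0.41 (SE 0.191, edgeR adjusted p = 0.847; lower in both replicate numbers). For macrophage-like cells it was 1.22 (SE 0.287, edgeR adjusted p = 0.304, DESeq2 adjusted p = 0.0692). Of the 19 classes, edgeR called 0, DESeq2 called 0, and 1 class, macrophage-like cells, lay under an unadjusted p of 0.05 (edgeR). The groups did not overlap in 4 classes: macrophage-like cells were above, and megakaryocyte-like, plasmacytoid dendritic cell-like and NK cell or ILC-like cells below WT, where chance gives 33.3% of classes. The exact permutation p of each of these 4 was 0.333, the smallest that 2 libraries against 2 allow. The sort, whose gates are not described, can set these shares. With each library clustered alone the sign turned for megakaryocyte-like cells (0.619) and macrophage-like cells (-0.53). In that clustering only YAP1 heterozygote replicate 2 had a conventional dendritic cell-like cluster (231 cells). Classes of the same name thus need not hold the same cells in each library. Erythroid progenitor-like cells ranged from 1.144% in WT replicate 1 to 3.906% in WT replicate 2, with both YAP1 heterozygote libraries between these values.

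**Figure D1:**
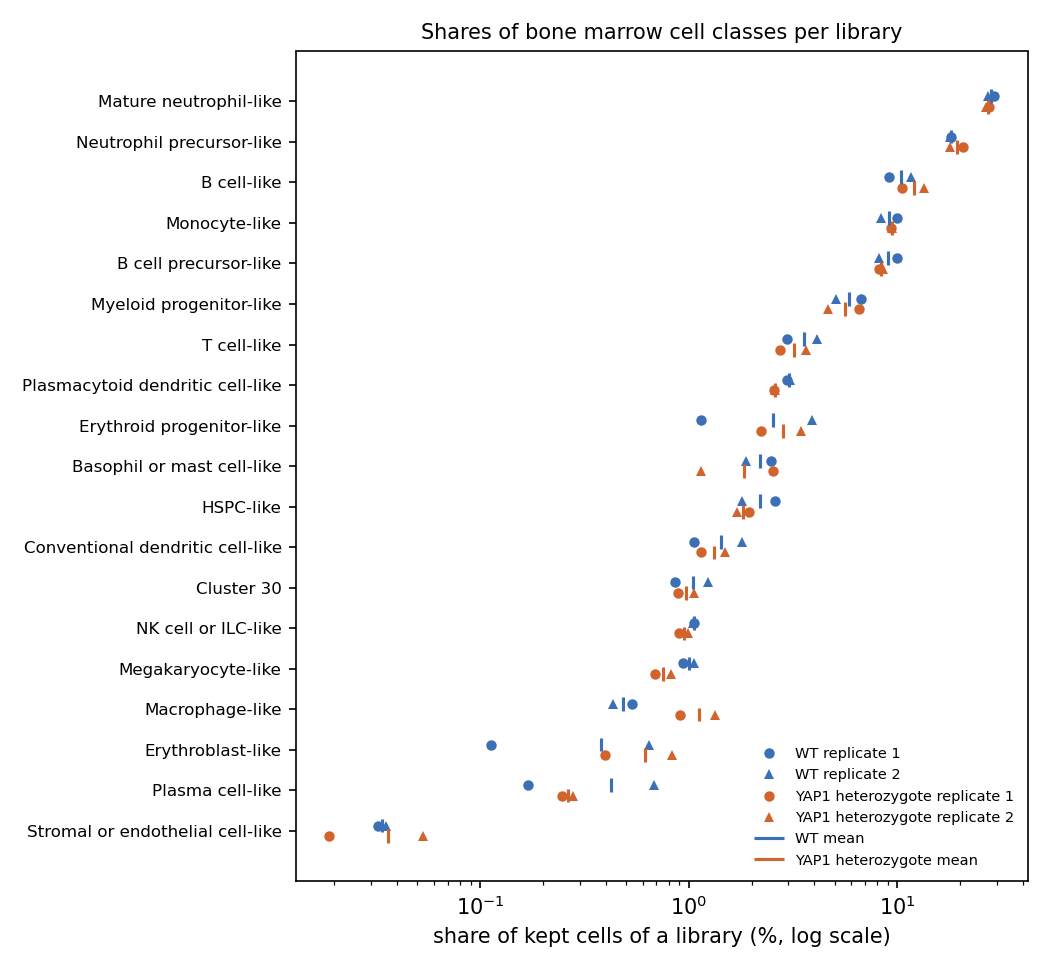
Share of kept cells (%, log scale) of each cell class; points are libraries, circles replicate 1, triangles replicate 2, and vertical bars the means of 2 libraries. The YAP1 heterozygote points of macrophage-like cells (0.909% and 1.34%) lie above both WT points and those of megakaryocyte-like cells (0.691% and 0.817%) lie below both.

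In megakaryocyte-like cells, Prss34, a basophil and mast cell protease (chromosome 17, 25298394 to 25300165), was the only gene called by edgeR, and DESeq2 called 1 gene too. It fell from 107 ± 56.9 CPM in WT to 4.44 ± 3.65 CPM in YAP1 heterozygote cells (log2 fold change -4.66, SE 0.487, adjusted p = 0.00726), but 311 of its 325 UMIs in WT replicate 1 and 165 of its 181 UMIs in WT replicate 2 came from 1 cell each. With the replicate block edgeR called 11 genes in this class. In the fit without it, 222 of the 9685 genes tested lay under an unadjusted p of 0.05, fewer than the share of 0.05 that chance alone gives. Without WT replicate 2 there were 19 calls, without YAP1 heterozygote replicate 1 there were 3, and without YAP1 heterozygote replicate 2 there were 5. The class held between 73 and 121 cells per library.

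Among gene lists, immediate early genes and S phase genes each rose in YAP1 heterozygote megakaryocyte-like cells by camera with the preset correlation. Of the 20 tested immediate early genes 19 were higher (median log2 fold change 0.346, camera adjusted p = 1.86e-13; adjusted p = 0.868 with an estimated correlation). Jun, an AP-1 transcription factor, stood at 2160 ± 216 CPM in WT and 2920 ± 503 CPM in YAP1 heterozygote cells, and its relative Jund at 995 ± 251 CPM and 1440 ± 307 CPM. No immediate early gene was called over all genes in this class (edgeR), and 4 rose adjusted over the list alone. The list's mean difference was 0.769 within replicate 1 and 0.047 within replicate 2. Of 41 S phase genes, which serve DNA replication, 36 were higher (median 0.175, camera adjusted p = 5.96e-09; adjusted p = 0.868 with an estimated correlation), with the chromatin gene Atad2 at 210 ± 6.01 CPM in WT and 247 ± 15.5 CPM, and Mcm6, part of the replicative helicase, at 201 ± 13.6 CPM and 219 ± 3.77 CPM. Nuclear oxidative phosphorylation genes rose slightly (37 of 44 higher, median 0.0669, camera adjusted p = 0.00228; adjusted p = 0.868 with an estimated correlation).

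The actomyosin list, which holds Myh9, fell slightly in megakaryocyte-like cells: 25 of 32 genes were lower (median -0.0747, camera adjusted p = 0.0333; adjusted p = 0.871 with an estimated correlation). The groups overlapped in the mean of this list, which lay at -0.0793 and 0.114 in WT and at -0.126 and 0.0914 in YAP1 heterozygote replicates 1 and 2. Its most highly expressed member Actb, beta-actin, stood at 5810 ± 346 CPM in WT and 5340 ± 497 CPM in YAP1 heterozygote cells. All 13 mitochondrially encoded transcripts were lower (median -0.0807, camera adjusted p = 0.0158; adjusted p = 0.871 with an estimated correlation). Platelet and megakaryocyte function genes did not pass (22 of 28 lower, median -0.109, camera adjusted p = 0.134). Nor did the YAP and TEAD target genes (5 of 7 tested genes lower, median -0.27, camera adjusted p = 0.0654), the megakaryocyte and erythroid transcription factors (10 of 17 lower, camera adjusted p = 0.231) or the Hippo pathway kinases and adaptors (7 of 14 lower, camera adjusted p = 0.647).

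Across the other classes, most called genes were lower in YAP1 heterozygote cells. In basophil or mast cell-like cells the neutrophil-attracting chemokine Cxcl2 fell from 1840 ± 892 to 359 ± 104 CPM (log2 fold change -2.44, adjusted p = 0.0241), the cytokine Tnf from 148 ± 17.6 to 47.4 ± 0.075 CPM (-1.72, adjusted p = 0.0043), and the lipid droplet protein gene Hilpda (-2.06) and the kinase gene Pim1 (-1.15) fell as well. In NK cell or ILC-like cells Tnfaip3, an inhibitor of NF-kB signalling, fell from 1110 ± 12.2 to 345 ± 78.1 CPM (-1.72, adjusted p = 0.0116), the stress-induced transcription factor Atf3 from 71.1 ± 17.1 to 11.2 ± 0.072 CPM (-2.67, adjusted p = 0.0464) and Nr4a1, a nuclear receptor induced by antigen receptor signalling, from 434 ± 67.7 to 138 ± 44.9 CPM (-1.67, adjusted p = 0.0405). Areg also met the rule there but leads cluster 7 of this class, and is not read as a change within it. Cluster 7, led by Gata3, Rora and Rnf128, gave 20 and 24 cells of this class in the WT libraries and 11 and 10 in the YAP1 heterozygote libraries. Cluster 24, led by Gzma, gave 112, 95, 84 and 121 cells. In cluster 24 alone, a test chosen after the data were seen, edgeR called 0 genes (306 under an unadjusted p of 0.05, 2 by DESeq2). Log2 fold changes there were -1.4 (SE 0.207) for Tnfaip3, -2.35 (SE 0.421) for Atf3 and -1.39 (SE 0.259) for Nr4a1, with adjusted p from 0.0754 to 0.149. T cell-like cells had lower Tnfaip3 (658 ± 181 against 303 ± 31.2 CPM), Nr4a1 (101 ± 17.8 against 48.5 ± 1.33 CPM), the costimulatory receptor Icos, the insulin signalling adaptor Irs2, the MAP kinase phosphatases Dusp5 and Dusp10, the endosomal sorting gene Vps37b, the Rab activator Dennd4a and the noncoding Lncpint, with log2 fold changes from -1.69 to -1.03 and adjusted p from 0.0167 to 0.0466. Macrophage-like cells had lower Tnfaip3 (276 ± 10.7 against 62.9 ± 18 CPM), Dusp5 (-3.38), the stress cytokine Gdf15 (-2.41) and Rgs1 (-1.73), a regulator of G protein signalling, with adjusted p from 0.00213 to 0.024. They had higher Olfm4 (4.92), a neutrophil granule protein gene, and Top2a (3.48), the topoisomerase of dividing cells. Of the UMIs in YAP1 heterozygote replicate 1, 37 of 39 of Olfm4 and 24 of 47 of Top2a came from 1 cell. Without the top cell of each library Olfm4 had too few counts for a fit and Top2a an adjusted p of 0.262. Cluster 30 had lower Cd83 (-1.76), an activation marker, and Thbs1 (-1.26), thrombospondin, both with an adjusted p of 0.0398. In B cell precursor-like cells the transcription factor Ets2 (-1.14), Dennd4a (-1.02) and Pcyt1a (-0.986), an enzyme of phosphatidylcholine synthesis, fell with adjusted p from 0.0164 to 0.0344. All adjusted p in this paragraph are from edgeR.

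The calls that rose were mainly hemoglobin genes. Hbb-bs rose from 44.5 ± 36.4 CPM in WT to 938 ± 127 CPM in YAP1 heterozygote T cell-like cells (adjusted p = 0.00112), and Hba-a1, Hba-a2 and Hbb-bt rose with it; the same 4 genes rose in cluster 30. In the T cell-like class 1321 of 1392 and 2106 of 2308 Hbb-bs UMIs of the YAP1 heterozygote libraries came from 1 cell each. Plasma cell-like cells had lower Prtn3 (501 ± 164 against 13.5 ± 3.53 CPM) and Fcnb (196 ± 124 against 4.86 ± 0.069 CPM), genes of the neutrophil lineage, and lower Nkg7 (log2 fold change -4.97), a cytotoxic granule gene. This class held 21, 77, 26 and 37 cells in the 4 libraries. In a single library 1 cell held up to 49.4% of the Prtn3, 63.6% of the Fcnb and 55.6% of the Nkg7 UMIs. Without the top cell of each library edgeR still called these genes (log2 fold changes -4.47, -4.78 and -7.74). Whether RNA of other cells shaped these falls was not tested. The other named genes of the class, Iglc1 and Ighg1, define the cluster and are not read as changes within it. The macrophage-like class carried 66700 ± 20300 CPM of S100a9, a neutrophil transcript, in WT and 81700 ± 1660 CPM in YAP1 heterozygote libraries.

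In all, edgeR called 55 genes over 17 classes (12 higher, 43 lower in YAP1 heterozygote cells) in 8 of them, with 7054 under an unadjusted p of 0.05. The classes had 3580 to 11873 tested genes each, and chance alone puts a share of 0.05 of them under this p. Counts under an unadjusted p are thus not read as changes beyond the calls. DESeq2 called 174. In the other 9 classes edgeR called 0, with 221 to 637 genes under an unadjusted p of 0.05. In these 9 classes DESeq2 called 0 to 21, and edgeR with the block 0 to 243. The block also takes out the difference that the sex-linked transcripts show between replicate numbers. The 0 calls of the fit without it are thus not read as an absence of changes. Over all cells summed edgeR called 0, with 420 of 15580 genes under an unadjusted p of 0.05 and 18 by DESeq2. The count was 616 without WT replicate 1, 2319 without WT replicate 2, 787 without YAP1 heterozygote replicate 1 and 591 without YAP1 heterozygote replicate 2, fits in which the lone library of a group is assumed to vary like the other group. When the cell with the most UMIs of a gene was left out of each library, 32 of the 55 calls were kept, among them 5 of 5 in basophil or mast cell-like, 8 of 8 in NK cell or ILC-like and 9 of 13 in T cell-like cells, but 0 of 8 in macrophage-like cells and 0 of 6 in cluster 30. In these 2 classes the loss of a call does not by itself show that 1 cell carried it. Log2 fold changes went from -2.41 to -2.04 for Gdf15, from -2.02 to -1.84 for Tnfaip3, from -1.73 to -1.39 for Rgs1 and from -3.38 to -2.39 for Dusp5 in macrophage-like cells. For Rgs1 and Dusp5 the top cell held up to 63.9% and 70.4% of the UMIs of a library. In cluster 30 they went from -1.76 to -1.77 for Cd83 and from -1.26 to -1.35 for Thbs1.

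NF-kB and inflammatory cytokine genes were lower in YAP1 heterozygote cells in almost every class. The list of 28 genes fell past the threshold in 16 of 17 classes, all but plasma cell-like cells, with median log2 fold changes between -1.16 in erythroid progenitor-like and -0.101 in neutrophil precursor-like cells (camera with the preset correlation). It passed in 0 of the 17 classes with an estimated correlation (adjusted p of at least 0.868). In basophil or mast cell-like cells 23 of 25 tested genes were lower (median -1.03, camera adjusted p = 4.05e-30), and Nfkbia, the NF-kB inhibitor that NF-kB itself induces, fell from 3100 ± 212 to 1520 ± 194 CPM. In NK cell or ILC-like cells 14 of 15 were lower (median -0.938), with Nfkbia at 758 ± 32.2 against 249 ± 3.13 CPM and Nfkbiz, a nuclear partner of NF-kB, at 404 ± 6.18 against 157 ± 23.5 CPM. In cluster 24 alone the log2 fold changes were -1.41 (SE 0.256, adjusted p = 0.142) for Nfkbia and -0.812 (SE 0.269, adjusted p = 0.815) for Nfkbiz (edgeR), against -1.64 and -1.4 in the whole class. There 9 of 14 list genes were lower (median -0.468, camera adjusted p = 4.26e-05 within the cluster; adjusted p = 0.518 with an estimated correlation). HSPC-like cells, the stem and progenitor cells, had 22 of 24 lower (median -0.698; Nfkbia 399 ± 98.4 against 192 ± 38.5 CPM, adjusted p = 0.0642), plasmacytoid dendritic cell-like cells 23 of 24 (median -0.989), mature neutrophil-like cells 21 of 25 (median -0.783) and megakaryocyte-like cells 16 of 22 (median -0.397; Nfkbia 140 ± 38.4 against 85.9 ± 2.22 CPM). In megakaryocyte-like cells neutrophil RNA made up at most 3.7% of UMIs in WT replicate 1 and 0.942, 1.01 and 2.14% in WT replicate 2 and YAP1 heterozygote replicates 1 and 2. Of 10 granulocyte alarmins 8 were lower there (median -0.43, camera adjusted p = 0.255). With neutrophil RNA taken off, a test chosen after the data were seen, the NF-kB list did not pass in this class (median 0.0149, camera adjusted p = 0.491). Over all genes, 9 members were called lower: 3 each in basophil or mast cell-like and NK cell or ILC-like cells, 2 in macrophage-like cells and 1 in T cell-like cells. Adjusted over the list alone, 21 members fell in basophil or mast cell-like, 18 in plasmacytoid dendritic cell-like, 13 in mature neutrophil-like, 12 in HSPC-like and 0 in megakaryocyte-like cells.

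With fry the lowest p of this list was 0.00145 (adjusted p = 0.236), so the calls rest on the preset correlation. By the mean of the list the groups did not overlap in 14 of 17 classes, with the YAP1 heterozygote libraries lower in all 14; chance gives no overlap, in either direction, in 33.3% of classes, and the classes share their libraries. It was lower within both replicate numbers in 15 classes. WT replicate 1 had the highest mean in most classes, and it held 92.4% of cluster 2, a group of mature neutrophil-like cells led by Cxcl2 and Clec4e. Without cluster 2 the list was still lower in mature neutrophil-like cells (median -0.718, camera adjusted p = 4.6e-12 within the class; edgeR called 0 genes, with 471 under an unadjusted p of 0.05), and without WT replicate 1 it fell in 15 of the 16 classes.

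**Figure D2:**
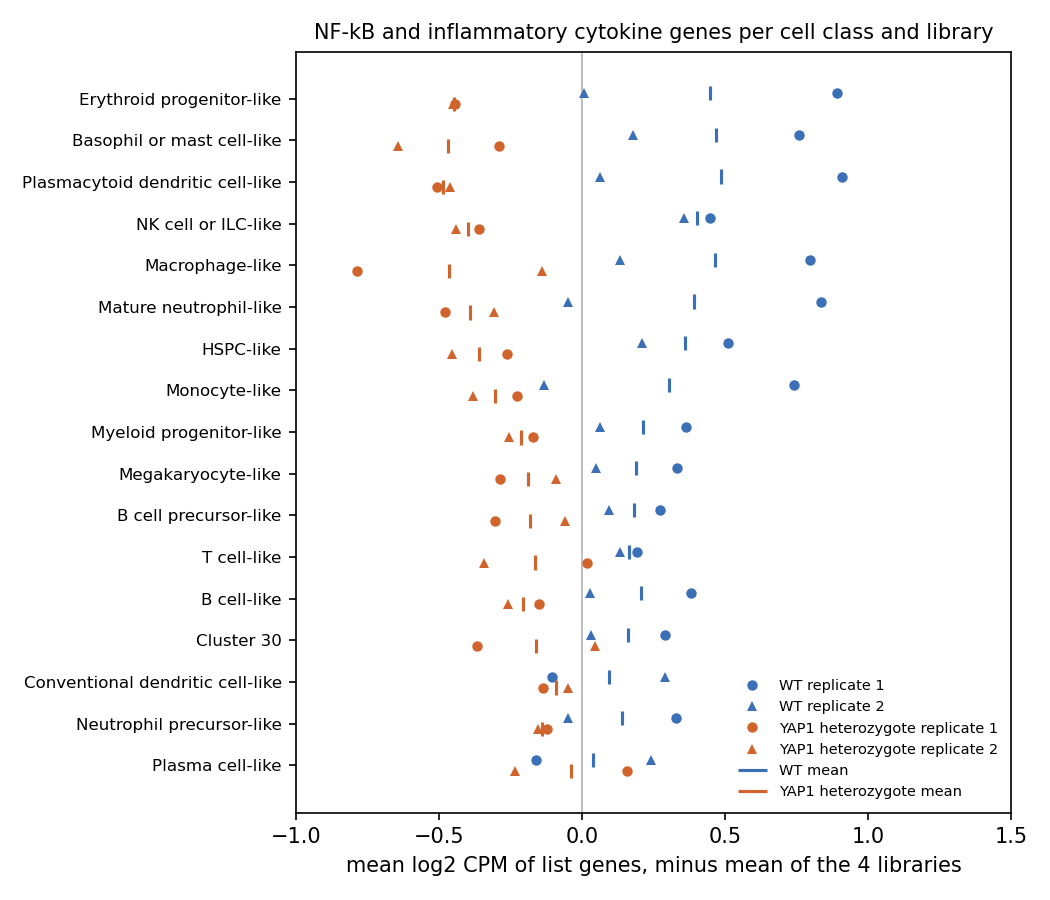
Mean log2 CPM of the tested NF-kB and inflammatory cytokine genes in each class, relative to the mean of the 4 libraries; points are libraries, circles replicate 1, triangles replicate 2, and vertical bars the means of 2 libraries. In 14 of the 17 classes both YAP1 heterozygote points lie to the left of both WT points.

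Immediate early genes, which cells induce within minutes of a stimulus or of tissue handling, moved in both directions. The list fell in 8 classes, with the lowest median in macrophage-like cells (-0.762), and rose in megakaryocyte-like, myeloid progenitor-like and cluster 30 cells. Junb, an AP-1 gene, fell from 3020 ± 62.1 to 1480 ± 242 CPM in NK cell or ILC-like cells (log2 fold change -1.07, adjusted p = 0.0405; -0.869 with SE 0.153 and adjusted p = 0.142 in cluster 24 alone), and stood at 1460 ± 198 against 933 ± 30.4 CPM in B cell-like cells. Every list call here had an adjusted p of at least 0.868 with an estimated correlation. Neutrophil granule genes moved alongside the NF-kB list in several classes: the secondary granule list fell in 8 classes, among them plasmacytoid dendritic cell-like (median -0.763) and B cell-like cells (median -0.592), and rose in 3. The alarmin list of granulocytes fell in 5 classes and rose in 1, the primary granule list fell in 3 and the maturation list in 1.

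Over all lists, 148 of 487 pairs of list and class passed (48 higher, 100 lower), and 0 passed with an estimated correlation (13 under an unadjusted p of 0.05, lowest adjusted p = 0.868) or with fry (28 under an unadjusted p of 0.05). Heat shock genes fell in 6 classes, apoptosis regulators, cholesterol biosynthesis genes and mitochondrially encoded transcripts in 4 each, platelet and megakaryocyte function genes in 3, and p53 targets and glycolysis genes in 2 each. The YAP and TEAD target genes passed in 1 class, T cell-like cells (5 of 7 lower, median -0.181, camera adjusted p = 0.0402; adjusted p = 0.868 with an estimated correlation), with overlap of the groups in the list's mean and the stress gene Gadd45b at 61.5 ± 0.547 against 32.7 ± 2.26 CPM, and the Hippo and the megakaryocyte and erythroid transcription factor lists passed in 0 classes. Hemoglobin and heme genes rose in 8 classes, nuclear oxidative phosphorylation genes in 6 and MHC class I genes in 1. Lists that moved both ways were ribosomal proteins (up in 5 classes, down in 1), S phase (5 and 5), G2 and M phase (4 and 7), MHC class II (2 and 5), actomyosin (3 and 2), interferon response (1 and 2), unfolded protein response (1 and 3), the B cell receptor list (1 and 6), the T cell receptor list (1 and 1) and the complement and macrophage list (3 and 1). The complement list fell in macrophage-like cells, whose markers it holds. The sex chromosome list passed in 0 classes, and the list of Yap1, Wwtr1 and Myh9 had too few genes for this test.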

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

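Of the tests on the 2 patterns weighed here, the fit without WT replicate 1 was planned but its use as a test of 1 deviating library was chosen after the result was seen, the neutrophil RNA test over 11 classes was added after the data were seen, with its bounds written before its own result, and those on tissue handling, on neutrophil RNA in megakaryocyte-like cells, on single droplets and on free hemoglobin were chosen after the result was seen as well.

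NF-kB and inflammatory cytokine genes were lower in YAP1 heterozygote cells of 16 of 17 classes. Without WT replicate 1 the list still fell past the threshold in 15 of the 16. This cannot decide on 1 deviating library, since these passes rest on the preset correlation and on 1 WT library. By the mean of the list, WT replicate 2 also lay above both YAP1 heterozygote libraries in 14 of 17 classes. WT replicate 1 thus did not carry the difference alone in these 14, though the classes share their libraries. Free neutrophil RNA was tested by taking off the most that S100a8 and S100a9 allow. Over 11 classes the list stayed past the threshold (camera with the preset correlation) in 10. The median log2 fold changes left in these 10 lay between -1.22 and -0.151, which argues against free neutrophil RNA as the whole cause there. Free RNA of other cell types was not taken off, so this test cannot decide on it. In megakaryocyte-like cells, set apart after this was seen, the camera adjusted p became 0.491. The median log2 fold change moved there from -0.397 (quartiles -0.745 and 0.0271) to 0.0149 (-0.452 and 0.531). In that class free neutrophil RNA is thus a candidate explanation. The neutrophil, myeloid progenitor-like, macrophage-like and cluster 30 cells were not tested for this. Stress during tissue handling cannot be told apart from other explanations in any class, since immediate early genes fell in 8 of the 16, rose in 3 and passed in neither direction in the other 5, and none of these list calls holds with an estimated correlation. The genotype remains a possible explanation as well, which these libraries cannot separate from an unlabelled difference in handling, since no batch is given in the labels. With 2 libraries per group and an adjusted p of at least 0.868 with an estimated correlation, the pattern is a hypothesis.

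Hemoglobin genes in T cell-like and cluster 30 cells and Prss34 in megakaryocyte-like cells made up 9 calls. Without the cell with the most UMIs of the gene in each library, edgeR called none of them: in T cell-like cells the log2 fold changes went from between 3.57 and 4.35 to at most 0.991 (SE 0.408; Hba-a2, 3.83 with SE 0.368 before), and in megakaryocyte-like cells Prss34 went from -4.66 (SE 0.487) to -0.844 (SE 0.627), so single droplets with RNA of another cell type may account for these 5 calls. In cluster 30 this remains open, since its folds stayed between 3.32 (SE 1.03) and 4.68 (SE 1.08; 5.51 with SE 0.652 before) and the calls ended with the wider error, and what is left rests mainly on YAP1 heterozygote replicate 2 (1614 of 3423 Hbb-bs UMIs left, against 23 of 451 in replicate 1). Free hemoglobin RNA is argued against as the whole cause in T cell-like cells, where 1 cell held at least 85.6% of the UMIs of each of the 4 genes in both YAP1 heterozygote libraries, but not in cluster 30, where the lowest such share was 49.3%. A part from free RNA stays open in both, since the share of cells with a Hbb-bs UMI rose within both replicate numbers (T cell-like 7.86 to 19.44% and 28.3 to 32.51%; cluster 30 6.54 to 21.28% and 39.01 to 40.71%), and no biological explanation was tested for this pattern.

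Further lists passed in opposite directions in 2 classes, with both YAP1 heterozygote libraries on 1 side of both WT libraries in each class; the difference between classes was not tested, and none of these calls holds with an estimated correlation. Median log2 fold changes were 0.256 in macrophage-like and -0.0919 in basophil or mast cell-like cells for actomyosin genes, 0.508 in conventional dendritic cell-like and -0.554 in macrophage-like cells for complement and macrophage genes, and 0.162 in cluster 30 and -0.0767 in basophil or mast cell-like cells for ribosomal proteins. Immediate early genes had 0.346 in megakaryocyte-like and -0.762 in macrophage-like cells. G2 and M phase genes had 0.92 in macrophage-like and -1.46 in plasma cell-like cells, and S phase genes 0.175 in megakaryocyte-like and -1.12 in plasma cell-like cells. Both the plasma cell-like class (Elane, 191 and 1459 UMIs in WT) and the macrophage-like class (S100a9, 66700 ± 20300 CPM in WT) carried transcripts of the neutrophil lineage. Whether RNA of other cells shaped these medians was not tested. MHC class II genes had 0.17 in conventional dendritic cell-like and -1.25 in NK cell or ILC-like cells. In the latter class Igkc (221 ± 61.9 against 90.7 ± 62.2 CPM) and Cd79a (50.3 ± 17.7 against 14.4 ± 14 CPM), transcripts of B cells, were lower too, without being called. Whether RNA of B cells shaped the MHC class II median there was not tested. Secondary granule genes had 0.393 in macrophage-like and -0.763 in plasmacytoid dendritic cell-like cells. T cell receptor genes had 0.257 in monocyte-like and -0.124 in HSPC-like cells, and unfolded protein response genes 0.263 in basophil or mast cell-like and -0.139 in neutrophil precursor-like cells.

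Barcodes with fewer than 200 genes, left out of the comparisons, made up 1.842% (Wilson interval 1.61 to 2.106%) and 2.076% (1.856 to 2.323%) of the barcodes of the YAP1 heterozygote libraries, against 0.529% (0.419 to 0.668%) and 1.607% (1.398 to 1.847%) in WT; the intervals of WT replicate 2 and YAP1 heterozygote replicate 1 overlap. Hemoglobin made up 71.65% and 87.32% of their UMIs in the YAP1 heterozygote libraries and 38.68% and 70.54% in WT.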

How the results depend on the processing

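Settings without the top cell of a gene, with neutrophil RNA taken off, without erythroid classes in the total, without cluster 2, with NK cell or ILC-like cells of cluster 24 alone and with both an estimated correlation and the block were chosen after the data were seen; the others were planned. No class share passed under any setting. The megakaryocyte-like share kept its sign except with each library clustered alone (0.619). There the megakaryocyte-like cluster of YAP1 heterozygote replicate 1 held 221 cells, against 73 in the report's clustering. The macrophage-like share turned there too (-0.53). Macrophage-like clusters held 264 and 278 cells in WT and 201 and 167 in YAP1 heterozygote libraries, against 66, 49, 96 and 177. Only YAP1 heterozygote replicate 2 had a conventional dendritic cell-like cluster, so these classes need not hold the same cells. The cause was not tested. Leaving out 1 library gave log2 fold changes of -0.537 to -0.295 for the first and 0.915 to 1.47 for the second, 0 changed classes, -0.0729 to 0.152 for Myh9 over all cells (a sign turned without WT replicate 2 and without YAP1 heterozygote replicate 1), 591 to 2319 called genes, 1 to 19 in megakaryocyte-like cells, 40 to 42 of the 42 named genes, 172 to 210 list calls and 15 to 16 classes with a lower NF-kB list.

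The 55 calls became 904 with the replicate block, 174 with DESeq2, 1394 with no filter on low counts, 20 with each library clustered alone and 117 without the top cell. In megakaryocyte-like cells the 1 call became 11 with the block, 32 with no filter, 2 with thinned sums, and 0 with the stricter cell filter, with each library clustered alone and without the top cell (edgeR; 222 genes under an unadjusted p of 0.05 in the report's fit, 1 by DESeq2). Of the 42 named genes, 32 were called by DESeq2, 29 with doublets kept, 26 with thinned sums, 23 with the stricter filter and 23 at Leiden resolution 2.0. With each library clustered alone 10 were called, and without the top cell 22. The direction was always the same where fitted, and the cause was not tested. Camera's 148 list calls and 16 classes with a lower NF-kB list became 0 with an estimated correlation, with or without the block, and 0 with fry (13 and 28 pairs under an unadjusted p of 0.05).

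The replicate numbers do not pair the libraries by the labels. By the sex-linked transcripts, however, same-numbered libraries were of the same kind in both groups. The block thus also takes out the difference between these kinds, which the report's fit leaves in the spread between libraries. Deviations of same-numbered libraries correlated across genes with a median of 0.16 over classes (-0.0301 to 0.284) and 0.392 over all cells. For the shares of the classes the correlation was 0.516. Counts of calls in the report's fit may be too low for that reason. The block also leaves fewer degrees of freedom to estimate the spread, however. Calls rose most in mature neutrophil-like cells (correlation 0.215, 0 to 243). They also rose where same-numbered libraries hardly correlated, in basophil or mast cell-like (0.0253, 5 to 23) and macrophage-like cells (0.000878, 8 to 24). In conventional dendritic cell-like cells (0.0306) they stayed at 0. The rise thus cannot be credited to the difference between kinds alone. Which fit comes nearer to the number of changed genes was not tested. In the 9 classes with 0 calls in the report's fit the block gave 0 to 243. It gave 171 list calls, 16 classes with a lower NF-kB list, 41 of 42 named genes, a megakaryocyte-like log2 fold change of -0.413 (adjusted p = 0.517) and 0 changed classes. Depth limits Yap1 and Wwtr1, with 13 and 29 UMIs in WT.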

Other observations

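The counts in this part were chosen after the data were seen.

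In every library the most abundant light chain of most plasma cell-like cells was Igkc. It led in 17 of 21 and 69 of 77 cells of the WT libraries, and in 25 of 26 and 37 of 37 of the YAP1 heterozygote libraries. Iglc1 led in 3 and 4 cells of the WT libraries and in 0 and 0 of the YAP1 heterozygote libraries. In the same order Iglc2 led in 1, 3, 1 and 0 cells and Iglc3 in 0, 1, 0 and 0. No difference was tested on these small counts. Ighg1 had 1323 and 4097 UMIs in the YAP1 heterozygote libraries, 1317 and 4096 of them in 1 cell each, and 0 UMIs in WT. Elane, a protease of the neutrophil lineage, had 191 and 1459 UMIs in WT and 15 and 14 in YAP1 heterozygote plasma cell-like cells, from 10, 25, 10 and 10 cells. In the WT libraries 102 of the 191 and 524 of the 1459 Elane UMIs came from 1 cell each.

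Leaving out the cell with the most UMIs of a gene raised the edgeR calls in some classes, most in basophil or mast cell-like cells, from 5 to 40, of which 37 were lower in YAP1 heterozygote cells. NK cell or ILC-like cells went from 8 to 23 calls, all 23 lower, and HSPC-like cells from 0 to 10, all 10 lower; among HSPC-like cells 467 genes lay under an unadjusted p of 0.05 and DESeq2 called 4 with every cell in place. Over the 17 classes the calls rose from 55 to 117. Leaving out the largest cell trims every gene in each library, which can narrow the spread between libraries. The added calls are thus not read as changes that single cells had hidden.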
